A study of Homo sapiens with 12 samples.

How the data were processed

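The series measured microRNAs (miRNAs) in MCF-7, an established line of human breast ductal carcinoma cells, with the NanoString nCounter miRNA assay, which counts fluorescent barcodes bound to each miRNA without amplification. Cells were held at 0.5% oxygen and then returned to normal oxygen. They were harvested at 0 h (the hypoxia control), 1 h, 12 h and 24 h of reoxygenation, with 3 samples per time and 12 in all. Total RNA was isolated with TRIzol and purified on RNeasy columns, per the labels' protocols. Groups and replicate numbers came from the sample titles. The labels do not say that the replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

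The deposited values are whole raw counts per probe, as the values themselves show: they are whole numbers of at least 1 whose totals and positive control levels differ between samples. The software version and any handling of background before deposit are not given in the sources used here. The table held 822 probes: 800 for human miRNAs, 6 negative controls, 6 positive controls, 5 for mRNAs (ACTB, B2M, GAPDH, RPL19, RPLP0) and 5 for non-human sequences. Names of miRNAs are those of the assay, and a probe that binds several miRNAs carries all their names. Closely related miRNAs, such as the members of the let-7 family, can bind each other's probes in part, so their separate values are uncertain. The files give no genome build or positions.

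Total counts per sample ran from 82742 to 235535 in 11 samples and were 13774 in 0 h replicate 2. Intervals on shares of counts are 95% binomial intervals (Wilson) and cover counting error only. No pair of replicates within a time was alike within sampling noise: the lowest chi-square per degree of freedom was 2.20.

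A miRNA was tested when its mean over the 12 samples exceeded the mean of the negative control values plus 2 SD, 34.2 counts. This left 137 of 800 miRNAs. The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest) after TMM normalization. All 4 times were fitted together with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts set 1 h, 12 h and 24 h against 0 h, the mean of these 3 times against 0 h, 12 h against 1 h and 24 h against 12 h. An F test covered all 4 times. Standard errors were taken as the absolute log2 fold change divided by the square root of F. A normalized count is the count divided by the effective (TMM) library size and multiplied by the mean effective size.

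miR-769-3p, miR-769-5p and miR-210 lay below the filter. Their values came from a fit of the 798 miRNAs that vary, with library sizes from the 137 tested, and were adjusted over 798. This fit was not the one planned for miR-769-3p, which was to share the fit of the tested miRNAs. Single values were compared with exact two-sided permutation tests. With 3 samples against 3 the smallest p is 0.1. Correlations across samples used 100000 permutations, and those within the times 20000.

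Before the data were examined, 16 lists of miRNAs were fixed, of which 11 had at least 3 tested members: hypoxia-associated miRNAs, the let-7 family, relatives of the miR-17-92 cluster, the epithelial miR-200 group, p53-responsive miRNAs, the miR-15/16 family, the miR-29 and miR-30 families, miRNAs abundant in luminal breast cells, miRNAs tied to oxidative stress, endothelial markers and embryonic or placental miRNAs. The other lists were miR-769, miR-210, stromal markers, haematopoietic markers and muscle, neural and liver markers. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, and an estimated correlation) and with fry, over 33 combinations of list and time against 0 h.

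The rule for naming miRNAs was also fixed before the data were examined. In each contrast against 0 h it takes up to 10 higher and 10 lower miRNAs past the threshold with no overlap between samples, filled to 10 by smallest p. It adds miR-769-3p, miR-769-5p, miR-210 and the 2 members of each list with the smallest p. For the other tests it takes the 10 with the smallest p, and over all samples the 10 most abundant.

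Before the data were examined, 13 other settings were chosen: DESeq2 1.42.0, limma without and with a trend and robust fitting, fits of only the groups compared, no filter, a mean of at least 100 counts, 6 other scalings and the replicate number as a block. Each of the 12 libraries was also left out in turn. After seeing the data, 3 more were added: scaling by the positive controls, a fit without 3 libraries that stood apart, and the level of miR-4454 and miR-720 as a covariate. Of these libraries, 0 h replicate 2 stood apart in its positive controls. The others, 1 h replicate 3 and 24 h replicate 1, had ordinary positive controls but the highest shares of miR-4454 and miR-720 and the lowest normalized ACTB counts. For the mRNA probes, scaling by RPLP0 was added as well. The set of ratios between mRNA probes and their adjustment over 10 ratios were also settled after seeing the data, as was the tolerance for the similarity of the times, 1 SD of its simulated values.

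The tests were checked on simulated counts made from the means and sizes of these samples, for 24 h against 0 h. Each miRNA was drawn on its own, without the deviations that some of these libraries share across miRNAs, so the rates below may be too favourable. Of 137 miRNAs, 30 were changed. The test called 29.5% of those changed 1.5-fold, 74.5% of those changed 2-fold, 99% of those changed 4-fold and 1.07% of the unchanged. In the fit of 798 miRNAs, which served miR-769-3p and miR-210, it called 11.6% at 1.5-fold, 42.5% at 2-fold and 93.1% at 4-fold of 200 changed, and 0.686% of the unchanged. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.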

Results

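MCF-7 cells, a human breast cancer line, were exposed to 0.5% oxygen and reoxygenated to find miRNAs that respond and that could act on NDRG1, a hypoxia-induced gene. The assay gave counts for 800 miRNAs in 3 samples each at 0 h, 1 h, 12 h and 24 h. In the counts of all 12 libraries pooled, the most abundant were miR-4454 (25.1% of all miRNA counts), miR-21-5p (14.4%), miR-720 (14.1%) and let-7a-5p (4.63%). At 0 h miR-21-5p was first, ahead of miR-4454 with 13361 normalized counts and miR-720 with 7373. miR-200c-3p, miR-125a-5p, miR-23a-3p, let-7g-5p, miR-93-5p and miR-15b-5p followed, at means of 2304, 1458, 1217, 1143, 1046 and 1013 counts. miR-21-5p, a widely expressed oncogenic miRNA, had 14745 ± 1086 normalized counts at 0 h and 12573 ± 1847 at 24 h (SD, n = 3 each).

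Several libraries stood apart. 0 h replicate 2 had 13774 counts, against 82742 to 235535 in the other 11, and a positive control mean of 40.5 counts against 404 to 812. miR-4454 and miR-720, both regarded as fragments of tRNA, made up 12.5% of miRNA counts in 0 h replicate 1 (95% interval 12.3% to 12.8%) and 67.6% in 24 h replicate 1 (67.4% to 67.8%). Their share was 63.6% in 1 h replicate 3, 50% in 12 h replicate 3, 46.4% in 24 h replicate 3 and 42.7% in 0 h replicate 2. Each time held libraries with low and with high shares.

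**Figure D1:**
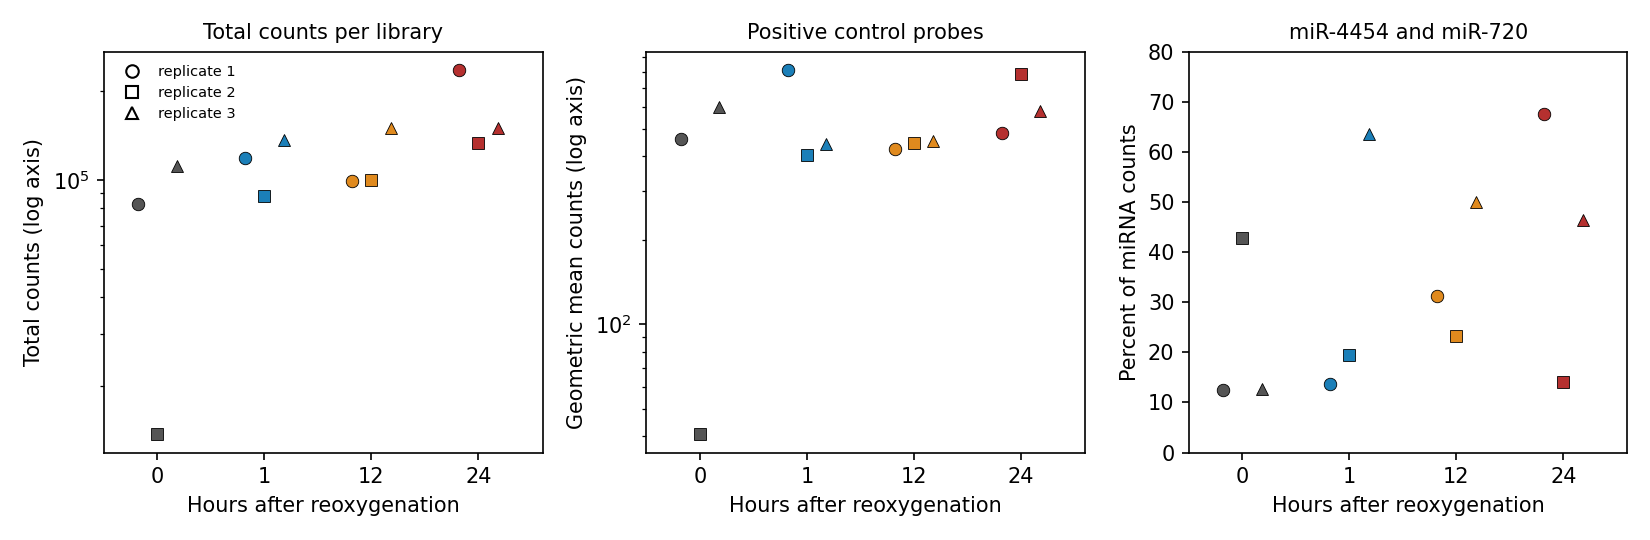
Total counts, geometric mean of the positive control probes (both on log axes) and percent of miRNA counts from miR-4454 and miR-720, for each library by hours after reoxygenation, with marker shape for the replicate. 0 h replicate 2 lies lowest in the first 2 panels, at 13774 and 40.5, and the share in the last panel runs from 12.5% to 67.6%.

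miR-769-3p, the miRNA the study put forward as a regulator of NDRG1, was counted near background in these samples. Its counts ran from 2 to 35. It exceeded the mean plus 2 SD of the sample's own negative controls in 3 of 12 samples. In 0 h replicate 2, among those 3, it had 2 counts against a limit of 1.98. Relative to 0 h its log2 fold change was 0.54 (SE 0.30) at 1 h, 0.72 (SE 0.29) at 12 h and 0.51 (SE 0.29) at 24 h. The other arm, miR-769-5p, gave -0.37, 0.17 and 0.14, with 1 of 12 samples above that level. By edgeR with Benjamini-Hochberg adjustment the adjusted p of miR-769-3p was 0.807, 0.724 and 0.674, so none of the 3 differences passed. Exact permutation tests of 3 against 3 gave p = 0.1, 0.1 and 0.2, where 0.1 is the smallest possible, and the 9 reoxygenated samples against the 3 controls gave an exact p = 0.0136. The study chose this miRNA on these samples, so that p is not independent evidence. The low-count control, 0 h replicate 2, also entered that test with only 2 counts. With scaling by library totals only, the 24 h value was -0.021, a scaling that moved the median of all tested miRNAs by -0.44.

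**Figure D2:**
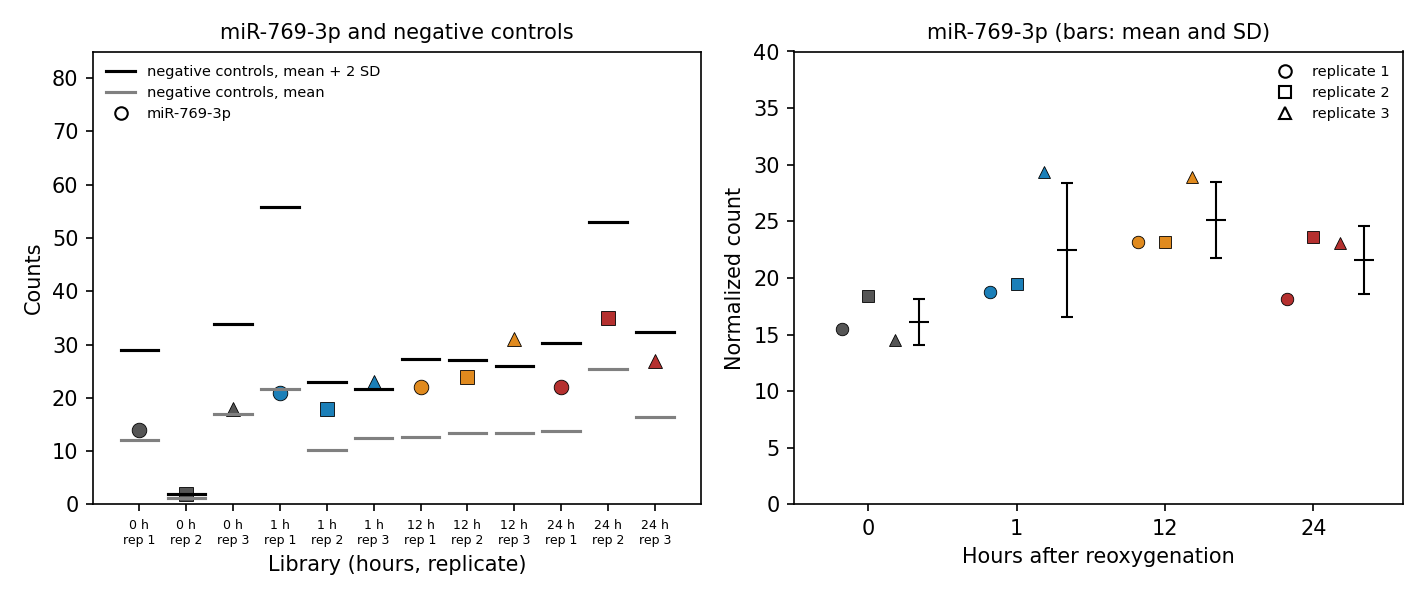
Left, counts of miR-769-3p (symbols) in each of the 12 libraries, with the mean of the negative control probes (grey lines) and that mean plus 2 SD (black lines). Right, its normalized count by hours after reoxygenation, with mean and SD of 3 samples. The counts run from 2 to 35 and exceed the black line in 3 libraries, among them 0 h replicate 2 with 2 counts.

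miR-210, which hypoxia-inducible factor 1 induces, was the hypoxia marker fixed in advance. Its log2 fold change against 0 h was -0.10 (SE 0.27) at 1 h, -0.62 (SE 0.27) at 12 h and -0.56 (SE 0.27) at 24 h. It averaged 33.2 counts. It exceeded the mean plus 2 SD of the sample's own negative controls in 8 of 12 samples. In 0 h replicate 2, among those 8, it had 4 counts against a limit of 1.98. The edgeR adjusted p (Benjamini-Hochberg) was 0.990, 0.803 and 0.674. The exact p of the 9 reoxygenated samples against the 3 controls was 0.0955.

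At 1 h of reoxygenation no miRNA passed the adjusted test against the hypoxia control. The largest tendencies with small p were higher miR-371a-3p (log2 fold change 0.80, SE 0.30), miR-575 (0.76), miR-429 (0.47) and miR-25-3p (0.41). Lower values were found for miR-1206 (-0.64), miR-505-3p (-0.62), miR-96-5p (-0.60), miR-32-5p (-0.37) and miR-29b-3p (-0.34). miR-640 gave -2.62, which came from a single control library, 0 h replicate 2: it held 984 normalized counts and the other 11 libraries 23.6 to 50.9. Without that library the value was 0.15. Without 1 h replicate 3, miR-96-5p stood at -0.32, miR-575 at 0.39 and miR-429 at 0.31. Without 1 h replicate 1, miR-371a-3p stood at 0.48 and miR-25-3p at 0.19, and without 0 h replicate 3 miR-32-5p at -0.23.

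By edgeR, 0 of 137 miRNAs passed at 1 h and 9 had an unadjusted p under 0.05, where chance gives 6.85. The lowest adjusted p (Benjamini-Hochberg) was 0.651. DESeq2 and both limma fits also gave 0. In 12 of 137 miRNAs the samples did not overlap, and chance gives 10%.

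Among the lists at 1 h, 7 of 10 hypoxia-associated miRNAs were lower, such as miR-23b-3p (-0.37) and miR-23a-3p (-0.22), and none passed. Without 1 h replicate 3 these stood at -0.15 and -0.027, and miR-23a-3p stood at -0.44 without 1 h replicate 2. Of 7 members tied to oxidative stress, 6 were lower, with miR-29b-3p at -0.34 and miR-34a-5p at -0.22. The let-7 family had 6 of 9 members higher, led by let-7i-5p (0.31) and let-7c (0.27). The miR-200 group had 4 of 7 higher, led by miR-429 (0.47) and miR-200b-3p (0.30), and relatives of miR-17-92 had 6 of 9 higher, led by miR-25-3p (0.41) and miR-363-3p (0.41). Of the p53-responsive miRNAs 4 of 5 were lower, with miR-107 at -0.16. The miR-15/16 family (miR-503 0.25 in the fit with normalized means of 30.7 at 0 h and 30.2 at 1 h, miR-15b-5p -0.15), the miR-29 and miR-30 families (miR-30e-5p 0.45) and the luminal list (miR-96-5p -0.60, miR-148a-3p -0.32) went both ways. The lowest camera adjusted p of any list at 1 h was 0.240, for the hypoxia-associated list, whose adjusted p was 0.623 with an estimated correlation.

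At 12 h the lower miRNAs included miR-34a-5p, a p53 target, and miR-29b-3p, a repressor of extracellular matrix genes. Their log2 fold changes against 0 h were -0.43 (SE 0.12) and -0.52 (SE 0.16). miR-324-5p (-0.80), miR-4516 (-0.79) and miR-505-3p (-0.56) were also lower, miR-4516 at -0.37 without 0 h replicate 1. miR-598 (0.73), miR-363-3p (0.68), miR-135a-5p (0.64) and let-7i-5p (0.41) were higher. miR-640 gave -2.87, again from 0 h replicate 2.

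None of these passed: edgeR gave 0 of 137 at 12 h, with 10 at an unadjusted p under 0.05 and a lowest adjusted p (Benjamini-Hochberg) of 0.381. DESeq2 and both limma fits gave 0, and samples did not overlap in 19 miRNAs, against 10% by chance. Without the 3 libraries that stood apart (0 h replicate 2, 1 h replicate 3 and 24 h replicate 1), 1 miRNA passed, miR-29b-3p at -0.59.

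The oxidative stress list had 6 of 7 members lower at 12 h, with a median of -0.21. By camera its adjusted p was 0.204, and 0.602 with an estimated correlation. Adjusted over the list alone, 2 members passed, miR-29b-3p and miR-34a-5p. miR-34a-5p alone passed in the p53-responsive list, where miR-16-5p stood at 0.17 and 4 of 5 members were higher although the list's test pointed lower. miR-29b-3p alone passed among the miR-29 and miR-30 families adjusted over the list alone, where miR-30e-5p stood at 0.33. In the let-7 family 7 of 9 members were higher, with let-7e-5p at 0.23. miR-200b-3p (0.34) and miR-141-3p (-0.21) of the miR-200 group went opposite ways, as did miR-363-3p and the probe for miR-106a-5p and miR-17-5p (-0.18). Of the hypoxia-associated miRNAs 6 of 10 were lower, with miR-27a-3p at -0.37 and the probe for miR-181b-5p and miR-181d at -0.30. Without 0 h replicate 2 these stood at -0.22 and -0.11, and the latter probe stood at -0.52 without 0 h replicate 1. In the luminal list 7 of 15 were higher, with miR-149-5p at 0.40 and miR-301a-3p at -0.27, and in the miR-15/16 family 3 of 5, with miR-503 at 0.46.

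At 24 h the differences from the hypoxia control were larger and still did not pass the adjusted test. miR-301a-3p was lower at 271 ± 22.9 normalized counts against 405 ± 39.2 at 0 h (SD, n = 3 each), a log2 fold change of -0.55 (SE 0.13). miR-34a-5p was lower at 234 ± 24.9 against 341 ± 41.8, or -0.51 (SE 0.12). miR-429, a repressor of the transcription factors ZEB1 and ZEB2, was higher at 115 ± 7.01 against 68.3 ± 10.2, or 0.77 (SE 0.20). miR-503, a relative of miR-16, was higher at 53.8 ± 2.92 against 30.7 ± 13.4, with a fitted value of 1.07 (SE 0.27).

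These 4 shared the lowest adjusted p of the edgeR test, 0.0791 after Benjamini-Hochberg adjustment. The others with the smallest p were let-7i-5p (0.48), let-7e-5p (0.37), miR-345-5p (0.63), miR-99a-5p (0.69), miR-374a-5p (-0.29) and miR-640 (-3.28, from 0 h replicate 2). In all, 0 of 137 passed by edgeR, DESeq2 and both limma fits, 19 had an unadjusted edgeR p under 0.05 (11, 23 and 21 by the other tools), and the samples did not overlap in 28, against 10% by chance. Without 1 h replicate 3, which enters only through the shared estimate of spread and the scaling, 4 passed: miR-301a-3p, miR-34a-5p, miR-429 and miR-96-5p. With the level of miR-4454 and miR-720 as a covariate, 4 passed: miR-34a-5p, miR-25-3p, miR-640 and miR-1183.

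**Figure D3:**
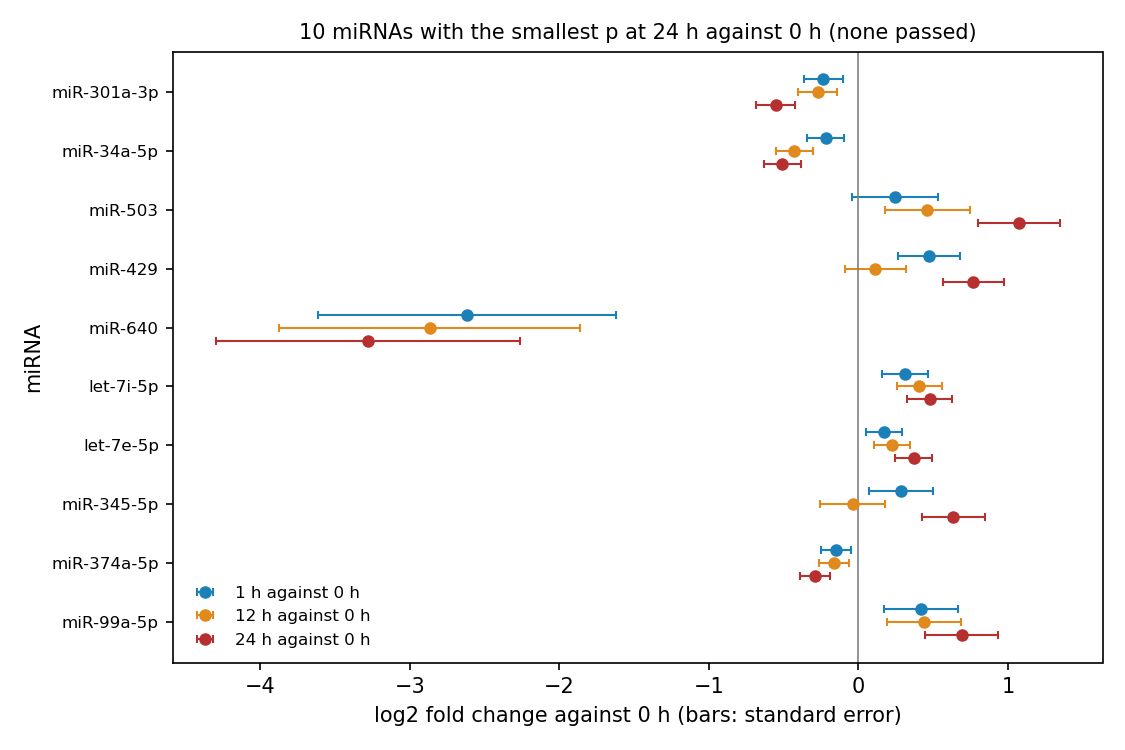
Log2 fold change against 0 h (horizontal axis, bars are standard errors) at 1 h, 12 h and 24 h for the 10 miRNAs with the smallest p at 24 h. miR-301a-3p, miR-34a-5p, miR-640 and miR-374a-5p lie below 0 at 24 h and the other 6 above, and none passed the adjusted test.

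The let-7 family, which represses RAS and other growth genes, had 8 of 9 members higher at 24 h, with a median log2 fold change of 0.28. let-7i-5p and let-7e-5p passed when adjusted over the list alone, and none when adjusted over all tested. By camera the list's adjusted p was 0.0919, and its unadjusted p with an estimated correlation was 0.0394 (adjusted p = 0.602). The fry test for a shift upward gave an adjusted p of 0.0739 and did not pass. The fry test for change in either direction gave an adjusted p of 0.0107. Under scaling by library totals only, 1 of 9 members was higher, with a median of -0.11 against -0.41 for all tested miRNAs. The list passed without 24 h replicate 3, at a camera adjusted p of 0.0108, and with the covariate, at 0.0362, and in the remaining settings its adjusted p ran from 0.0535 to 0.651. With an estimated correlation the values of 0.0108 and 0.0362 became 0.286 and 0.522, so neither pass held.

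Several lists share members: all 7 tested members of the oxidative stress list (miR-34a-5p, miR-29b-3p, miR-21-5p, miR-200c-3p, miR-141-3p, miR-92a-3p and miR-155-5p) also belong to another list. Of 7 miRNAs tied to oxidative stress, 6 were lower at 24 h (median -0.24, camera adjusted p 0.240), and 1 passed adjusted over the list alone, miR-34a-5p. miR-34a-5p also passed alone in the p53-responsive list, miR-429 in the miR-200 group, miR-503 in the miR-15/16 family and miR-301a-3p in the luminal list, each adjusted over the list alone. In the p53-responsive list 4 of 5 members were higher, with miR-16-5p at 0.24, while the test pointed lower. In the luminal list 8 of 15 were lower, among them miR-96-5p (-0.67). The hypoxia-associated list had 6 of 10 lower, led by miR-23b-3p (-0.46) and miR-27b-3p (-0.32). Relatives of miR-17-92 went both ways, with miR-19a-3p at -0.70 and miR-25-3p at 0.43, and the miR-29 and miR-30 families did too, with miR-29b-3p at -0.31 and miR-30e-5p at 0.33. The miR-200 group had 5 of 7 higher, with miR-200b-3p at 0.21. That value was 0.080 without 24 h replicate 1 and 0.12 without 0 h replicate 1.

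Markers of other cell types were mostly near background. Of the stromal probes 1 of 12 was tested, of the haematopoietic 2 of 11, of the muscle, neural and liver 2 of 12 and of the embryonic or placental 3 of 45. The tested stromal probe, miR-143-3p, stood at -0.31 at 1 h, 0.49 at 12 h and 0.90 (SE 0.80) at 24 h. The 3 endothelial probes averaged 64.9 to 92.3 counts and had a camera adjusted p of 0.794, 0.961 and 0.899 at 1 h, 12 h and 24 h. miR-126-3p stood at 0.11, 0.13 and 0.16 at 1 h, 12 h and 24 h. miR-222-3p stood at 0.074 at 1 h and -0.18 at 24 h, and miR-221-3p at a fitted -0.18 at 12 h, where its normalized means were 67.4 at 0 h and 68.4 at 12 h. Of the embryonic or placental probes, the one for miR-517c-3p and miR-519a-3p stood at 0.53, 0.47 and 0.43, miR-302d-3p at 0.41 at 1 h, and miR-519e-3p at 0.80 and 1.20 at 12 h and 24 h. The miR-517c-3p probe stood at -0.057 at 1 h without 1 h replicate 3. With the level of miR-4454 and miR-720 as a covariate, it stood at -0.051 and -0.20 at 12 h and 24 h, and miR-519e-3p at -0.21 and -0.29. With each library left out, miR-519e-3p ran from 0.32 to 1.19 at 12 h and from 0.28 to 1.64 at 24 h, where 24 h replicate 1 carried most of it.

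With the 3 reoxygenated times combined against hypoxia, the smallest p again belonged to lower miR-34a-5p (-0.39, SE 0.10) and miR-640 (-2.92, from 0 h replicate 2). miR-301a-3p (-0.35), miR-29b-3p (-0.39), miR-505-3p (-0.62) and miR-96-5p (-0.51) were lower. let-7i-5p (0.40), let-7e-5p (0.25), miR-429 (0.45) and miR-503 (0.59) were higher. By edgeR 0 of 137 passed, 14 had an unadjusted p under 0.05, and the lowest adjusted p (Benjamini-Hochberg) was 0.172. DESeq2 and both limma fits gave 0. Among other list members, miR-363-3p (0.48), miR-30e-5p (0.37), miR-25-3p (0.34), miR-200b-3p (0.28), miR-16-5p (0.14), miR-126-3p (0.13), miR-519e-3p (0.96) and the probe for miR-517c-3p and miR-519a-3p (0.48) were higher. miR-23b-3p (-0.35) and miR-23a-3p (-0.20) were lower. The study miRNA miR-769-3p stood at 0.59 and miR-210 at -0.42. The fitted values of miR-221-3p (-0.12) and miR-769-5p (-0.022) have no clear direction, since their normalized group means gave the opposite sign. miR-640 alone passed with no filter, without 0 h replicate 1, without 0 h replicate 3, with library totals only and with the covariate.

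Over the 4 times, the F test ranked miR-34a-5p, miR-503, miR-429, miR-301a-3p, miR-345-5p, miR-570-3p, miR-640, miR-148a-3p, miR-324-5p and miR-4516 first. By edgeR 0 of 137 passed, 16 had an unadjusted p under 0.05 and the lowest adjusted p (Benjamini-Hochberg) was 0.294. DESeq2 and both limma fits gave 0.

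Between 1 h and 12 h, miR-1234 (-1.26, SE 0.38), miR-4516 (-0.92), miR-324-5p (-0.73), miR-575 (-0.70), miR-371a-3p (-0.69) and let-7c (-0.33) were lower at the later time. miR-598 (0.78), miR-135a-5p (0.47), miR-148a-3p (0.45) and miR-183-5p (0.36) were higher. Without 1 h replicate 3, miR-1234 stood at -0.76, miR-575 at -0.33 and miR-183-5p at 0.18. miR-371a-3p stood at -0.36 without 1 h replicate 1 and miR-135a-5p at 0.27 without 1 h replicate 2. Between 12 h and 24 h, miR-570-3p (0.80, SE 0.24), miR-324-5p (0.68), miR-345-5p (0.67), miR-429 (0.66), miR-503 (0.62) and let-7c (0.42) were higher. miR-19a-3p (-0.72), miR-7-5p (-0.70), miR-454-3p (-0.52) and miR-148a-3p (-0.50) were lower. None passed: edgeR, DESeq2 and both limma fits gave 0 for each pair of times. The unadjusted edgeR counts were 7 and 13, and the lowest adjusted p (Benjamini-Hochberg) 0.423 and 0.230. Without the 3 libraries that stood apart, miR-143-3p (2.98), the tested stromal marker, and miR-598 (1.13) passed between 1 h and 12 h.

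The fold changes of the 3 times resembled each other across the 137 miRNAs, which are not independent replicates. Pearson's r was 0.734 for 1 h and 12 h, 0.823 for 1 h and 24 h and 0.790 for 12 h and 24 h. Unchanged groups simulated against the same controls gave means of 0.539, 0.568 and 0.558 and highest values of 0.827, 0.780 and 0.823, so the r of 1 h and 24 h alone lay above its simulated range. The covariances were 0.107, 0.151 and 0.151, against simulated means of 0.0601, 0.0633 and 0.0622, with a simulated range up to 0.170, 0.174 and 0.170, so all 3 lay inside. The 3 controls are too few to give each time controls of its own, and the simulated groups shared their controls in the same way. The simulation drew each miRNA on its own. Some real libraries deviated from their group means together, at r = 0.733 for 1 h replicate 3 with 24 h replicate 1. The simulated range may thus be too narrow, and an r above it does not show a shared response. Without miR-640, r was 0.566, 0.727 and 0.671. Without 1 h replicate 3 the r of 1 h with 12 h was 0.366 and with 24 h 0.336.

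The 5 mRNA probes of the assay gave a view beside the miRNAs. GAPDH, a glycolytic enzyme that hypoxia induces, had 3271 ± 459 normalized counts at 0 h, 2847 ± 1573 at 1 h, 2079 ± 132 at 12 h and 1370 ± 264 at 24 h (SD, n = 3 each). All 3 samples at 24 h lay below all 3 at 0 h, a log2 difference of -1.27, with an exact p = 0.1, the smallest possible. Over the 4 times the exact permutation p was 0.0944, or 0.472 adjusted over the 5 probes. The ratio of GAPDH to RPLP0, a ribosomal protein gene, fell from 1.52 ± 0.315 at 0 h to 0.707 ± 0.0417 at 24 h, with an exact permutation p over the 4 times of 0.000909 and of 0.00909 adjusted over the 10 ratios between mRNA probes. That ratio was singled out after its values were seen. None of the other 9 ratios passed. GAPDH to RPL19 and GAPDH to B2M each had an adjusted exact p of 0.0801. For GAPDH to ACTB it was 0.206, with a log2 difference of -0.867 at 24 h. ACTB (exact p = 0.960), B2M (0.369), RPL19 (0.274) and RPLP0 (0.892) did not differ detectably over the times. ACTB was at 171 normalized counts in 1 h replicate 3, against 1206 ± 190 at 0 h.

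**Figure D4:**
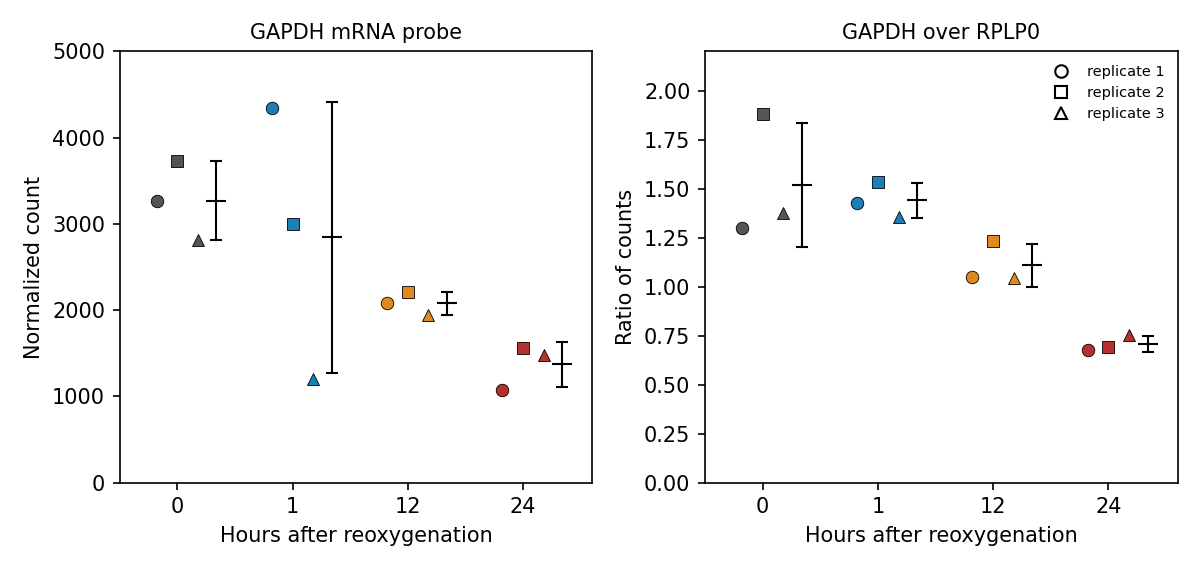
Normalized count of the GAPDH mRNA probe (left) and ratio of GAPDH to RPLP0 counts (right) for each library by hours after reoxygenation, with mean and SD of 3 samples. The ratio is 0.707 ± 0.0417 at 24 h against 1.52 ± 0.315 at 0 h.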

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

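The tests of RNA loss, of the low-count library, of scaling and of reoxygenation for GAPDH, and the test of RNA quality for miR-4454 and miR-720, were chosen only after the result was seen, as were the correlation of GAPDH with miR-4454 and miR-720, the correlations within the times and the test of what the regroupings followed.

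The GAPDH mRNA probe lies outside the miRNA measurement, and its ratio to RPLP0 was lower at 24 h than in all 3 hypoxia controls, by a log2 difference of -1.08. Loss of mRNA in poorer RNA was tested on GAPDH alone, not on the ratio. That test cannot exclude such loss as the source of the GAPDH difference, since the level of miR-4454 and miR-720 is only a possible stand-in for RNA quality. With the level of miR-4454 and miR-720 as a covariate that difference remained -0.985 (SE 0.366), against -1.27 (SE 0.417) without it. Such loss stays open. The level of miR-4454 and miR-720 correlated with GAPDH at r = -0.657 (permutation p = 0.024, adjusted over 5 relations 0.040). Spearman's rho was -0.706 (permutation p = 0.0136). Within the times r was -0.639 (permutation p = 0.0956), and without the 2 farthest libraries -0.350 (permutation p = 0.312). The mean log2 level was 1.34 higher at 24 h than at 0 h. The ratio at 24 h was 0.676, 0.691 and 0.755 in libraries where miR-4454 and miR-720 took 67.6%, 14% and 46.4% of miRNA counts. At 0 h the ratio was 1.3, 1.88 and 1.38 at shares of 12.5%, 42.7% and 12.6%. At 1 h it was 1.43, 1.54 and 1.36 at shares of 13.7%, 19.6% and 63.6%. At 12 h it was 1.05, 1.23 and 1.04 at shares of 31.3%, 23.2% and 50%. The low-count control did not carry the GAPDH difference, since without 0 h replicate 2 that difference was -1.16. Scaling by the miRNA counts does not enter the ratio to RPLP0, which had an exact permutation p of 0.000909 (0.00909 adjusted over 10 ratios). That ratio was singled out after its values were seen. The ratios to RPL19, B2M and ACTB need no scaling either. They differed by -1.53, -1.78 and -0.867 at 24 h, and none passed (adjusted exact p 0.0801, 0.0801 and 0.206). Scaling is thus unlikely as the whole source. A part from it stays open, as the ratio to RPLP0 differed by -1.08 and GAPDH by -1.27. A decline with reoxygenation time may account for the GAPDH difference and stays open as a hypothesis, since GAPDH on its own had an exact permutation p of 0.0944.

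miR-4454 and miR-720 took from 12.5% to 67.6% of the miRNA counts of a library. Reoxygenation time is unlikely as the whole source, since libraries of a single time ran from 12.5% to 42.7% at 0 h and from 14.0% to 67.6% at 24 h, and the exact permutation p over the 4 times was 0.724. Poorer RNA in some libraries is a candidate explanation: the ratio correlated with ACTB at r = -0.700 within the times (permutation p = 0.0379) and -0.664 over all (p = 0.00405, adjusted over 5 relations 0.0101; Spearman's rho -0.615, permutation p = 0.0376). Without the 2 libraries farthest from the median level, 24 h replicate 1 and 1 h replicate 3, r was -0.427 (permutation p = 0.221), so the relation is not shown among the rest. These 2 hold the highest levels. Leaving them out narrows the range, so the weaker r cannot tell an effect of few libraries from a general relation. Of the mRNA probes only ACTB and GAPDH were set against the level. In 1 h replicate 3 and 24 h replicate 1, RPLP0 was at 889 and 1581 normalized counts, against 2181 ± 286 at 0 h. B2M was at 184 and 171 against 155 ± 36.1, and RPL19 at 755 and 872 against 799 ± 91.1. B2M and RPL19 thus gave no sign of a general loss of mRNA. Low counts of a library stay open. Against the positive controls r was -0.317 (permutation p = 0.374) and rho -0.350 (permutation p = 0.269). Without the 2 libraries farthest in positive controls, 0 h replicate 2 (40.5 counts) and 1 h replicate 1 (812 counts), r was -0.325. Within the times r was -0.607 (permutation p = 0.0201).

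miR-769-3p stood slightly higher after reoxygenation, at an exact p of 0.0136 for 9 samples against 3, which leaves a response to reoxygenation open. The control 0 h replicate 2 entered that test with only 2 counts. A drift of the background has less in its favour: the negative control and non-human probes differed by -0.160 (SE 0.154 over probes), against 0.397 for miR-769-3p on the same scale. That SE does not cover the spread between libraries. In 0 h replicate 2 the negative controls averaged 1.17 counts, near the lowest value of 1, so the comparison is not firm. Noise of probes at this count level also stays open, since 13 of 198 miRNAs with a similar mean count, or 6.57%, had a difference as large. The values cannot choose between a response and noise and do not exclude a drift, and the study chose this miRNA on these samples.

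With a real count of 0, any split of the samples gives at least as many changed miRNAs, so splits say nothing about these counts. That covers the 5 pairs of times, where 10 of 10 splits did and the highest other count was 0 (10 splits are also too few for a share under 0.05). It also covers the 3 times together against 0 h and the test over the 4 times, where 100 of 100 regroupings did, with highest other counts of 9 and 5. The 16 miRNAs at an unadjusted p under 0.05 over the 4 times were matched by 14 of 100 regroupings, so chance cannot be excluded for that count. The highest other count was 44 and the median 7, which points to a structure of the samples other than time. Libraries alike in their level of miR-4454 and miR-720 are a candidate source: over 99 regroupings of the same 12 libraries, the count of other miRNAs rose with the F statistic of that level, at Spearman's rho = 0.688. The regrouping with 44 ranked 4 of 99 on that statistic, and what made these libraries alike was not shown.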

How the results depend on the processing

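The covariate, the fit without 3 libraries, and the positive control and RPLP0 scalings were chosen after seeing the data. Of 124 named fold changes under these and the settings chosen in advance, 3300 of 3380 values kept their direction and side of the threshold, 17 passed it and 63 reversed. The pseudocount alternatives were for normalized values and were not run, as the values are raw counts. The cause of the changes below was not tested, except that fewer samples or miRNAs enter some fits.

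The count of changed miRNAs was 1 in place of 0 with library totals only for 1 h, 12 h and 24 h against 0 h, for the times together and over the 4 times, each time miR-640. For the times together it was also 1 with no filter and 1 with the covariate, and ran from 0 to 1 when each library was left out. For 24 h against 0 h it was 4 with the covariate and ran from 0 to 4 with a library left out, 4 being without 1 h replicate 3. Without the 3 libraries it was 1 for 12 h against 0 h and 2 for 12 h against 1 h. For 24 h against 12 h it was 0 in every alternative run. The number of lists past camera was 1 in place of 0 with a mean of at least 100 counts (oxidative stress, 12 h) and with the covariate (let-7, 24 h), and ran from 0 to 1 with a library left out. With an estimated correlation the camera adjusted p of these lists was 0.183 for oxidative stress, and for let-7 0.522 with the covariate and 0.286 without 24 h replicate 3, so none passed. miR-769-3p at 24 h was -0.021 with library totals only. GAPDH at 24 h was -1.76 with library totals only. The r of 1 h and 24 h was 0.707 with no filter. With a library left out r ran from 0.366 to 0.809 for 1 h and 12 h, from 0.336 to 0.859 for 1 h and 24 h and from 0.671 to 0.834 for 12 h and 24 h.

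The replicate numbers gave no sign of pairing the samples. Deviations of samples with the same number had a mean correlation of 0.0029, and 8 of 18 pairs were over 0.1. For different numbers the mean was -0.00159, and 17 of 36 pairs were over 0.1. Of 12 samples, 4 correlated best with their own number. Some libraries with different numbers deviated together, at r = 0.733 for 1 h replicate 3 with 24 h replicate 1, which could hide a pairing. With the replicate number as a block the counts of changed miRNAs were 0 for all 7 tests and 0 lists passed.

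Other scalings moved the median log2 fold change of the tested miRNAs by over 0.1. Against 0 h at 1 h, 12 h and 24 h, library totals moved it by -0.19, -0.27 and -0.44 and mRNA probe scaling by 0.31, 0.18 and 0.23. Median scaling moved it by 0.19 at 12 h, and positive control scaling by -0.27 at 1 h and 0.11 at 12 h.

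Reversed values under library totals only were, at 1 h, miR-503 -0.065, miR-126-3p -0.10 and miR-222-3p -0.080. At 12 h they were miR-769-5p -0.21, let-7e-5p -0.046, miR-16-5p -0.079 and miR-126-3p -0.18. At 24 h they were let-7e-5p -0.044, miR-769-5p -0.41, miR-200b-3p -0.26, miR-16-5p -0.17, miR-30e-5p -0.18, miR-126-3p -0.27, the probe for miR-517c-3p and miR-519a-3p -0.20 and RPL19 -0.23. For the times together they were let-7e-5p -0.035, miR-200b-3p -0.036, miR-16-5p -0.13, miR-126-3p -0.18 and the miR-517c-3p probe -0.019.

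Under mRNA probe scaling, 1 h values reversed for miR-32-5p (0.031), miR-210 (0.29), miR-23a-3p (0.0089) and miR-34a-5p (0.085), as did miR-221-3p at 12 h (0.076) and miR-222-3p at 24 h (0.11). For the times together miR-769-5p (0.25), miR-23a-3p (0.0092) and miR-221-3p (0.18) reversed. Under positive control scaling at 1 h, miR-503 was -0.053, miR-126-3p -0.11 and miR-222-3p -0.20, and let-7c was 0.022 for 12 h against 1 h. With no filter miR-126-3p was -0.0078 and miR-222-3p -0.035 at 1 h. With a mean of at least 100 counts miR-210 at 1 h was 0.011 and miR-769-5p for the times together 0.055. Under median scaling the probe for miR-106a-5p and miR-17-5p was 0.030 and RPLP0 0.021 at 12 h, and miR-769-5p for the times together 0.029. Under both limma fits miR-221-3p was 0.19 at 12 h, and for the times together it was 0.24 and miR-769-5p 0.28. With the covariate the miR-517c-3p probe was -0.051 at 12 h, -0.20 at 24 h and -0.068 for the times together, and miR-519e-3p -0.21, -0.29 and -0.22. Without the 3 libraries miR-640 was 0.047, miR-107 0.11 and the miR-517c-3p probe -0.054 at 1 h.

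With each library left out in turn, 62 of the 127 fold changes of named miRNAs and miR-769-3p reversed or moved by over 1.5 times at least once. That of miR-769-3p at 1 h was 0.33 without 1 h replicate 3. The 1 h values ran from -3.32 to 0.15 for miR-640, from -0.17 to 0.014 for miR-210, from -0.11 to 0.18 for miR-222-3p, from -0.33 to 0.11 for miR-107, from -0.40 to 0.15 for miR-15b-5p and from -0.057 to 0.84 for the miR-517c-3p probe. For the times together they ran from -0.090 to 0.12 for miR-769-5p and from -0.29 to 0.037 for miR-221-3p.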

Other observations

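A shared decline of hypoxia-linked signals was tested as a hypothesis: miR-210, which hypoxia-inducible factor 1 induces, and the GAPDH to RPLP0 ratio may fall together on reoxygenation. Across the 12 libraries they correlated at Pearson's r = 0.590 (permutation p = 0.0454, 0.0568 adjusted over 5 relations) and Spearman's rho = 0.539 (permutation p = 0.0734). Without the 2 libraries farthest from the median ratio, 24 h replicates 1 and 2, r was 0.276 (permutation p = 0.443), so the relation is not shown among the rest. These 2 hold the lowest ratios. Leaving them out narrows the range, so the lower r cannot tell an effect of few libraries from a general relation. Within the times r was -0.169 (permutation p = 0.587), so no relation was shown from library to library at one time. With 3 libraries per time and miR-210 near background, that r cannot exclude one. It also does not bear on a shared fall between the times.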
